A study of Camellia sinensis with 2 samples.

How the data were processed

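Small RNA of mature tea leaves was measured in 2 libraries, 1 non-acclimated and 1 cold-acclimated, grouped by the treatment given in the labels. Per the labels, total RNA was extracted with Trizol and treated with DNase, small RNAs of 18 to 30 nt were cut from a denaturing gel, ligated to adapters, reverse transcribed, amplified by PCR and sequenced on an Illumina Solexa instrument. The aligner, its settings, the mismatches allowed and the releases of Rfam and miRBase are not given in the sources used here.

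For each library 3 deposited files were used, without header lines: sequences matched to Rfam (rRNA, tRNA, snRNA and snoRNA), to assembled transcripts and to miRBase. In the deposited files identical reads had been collapsed to distinct sequences, and the read count of each sequence is a raw count that was not normalized. The deposited miRBase file also gives an alignment score by the authors, which in every row equals 2 times the matched bases minus the mismatches minus 3 times another alignment count, and which was used only to understand the columns. The file described as a genome match holds hits on assembled transcripts named Unigene, with both ends included in the positions. The hits were taken to be without mismatch, since the overlapping sequences disagreed at 0 of 3322202 covered positions. Each miRBase-matched sequence has 1 listed match, with at most 2 mismatches. No genome was used, and the transcripts have no gene names in the files.

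The denominator of ratios, and of shares unless the text names another, was the number of reads in the union of the 3 files, each sequence counted once, which was 2476893 for the non-acclimated and 2212636 for the cold-acclimated library. These are parts of the libraries: sequence numbers follow falling read counts, with 0 exceptions among the listed sequences, and if this also holds for the numbers not listed, their reads can be bounded from their neighbours, which gives at least 14799078 and 10531268 reads in all. In both libraries sequence number 1 is not in the files. Reads were summed per miRNA family, taken from the authors' family column without its suffix, or from the miRNA's number where that column was undefined. By that column miR157 counts with miR156, miR165 with miR166 and miR170 with miR171. A match to a name with an asterisk was counted as the star strand. A read on several transcripts was divided evenly among its hits. Where transcripts were compared by their reads, sequences matched to Rfam or miRBase were left out.

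With 1 library per group there is no replicate error, so no test of the conditions was made and no p-value is given. A ratio of 2 libraries has the exact conditional binomial 95% interval, and a share the exact Clopper-Pearson 95% interval. Amplified reads without molecular identifiers are not independent molecules, and both intervals cover counting error only. Families with at least 100 reads over both libraries were called higher or lower by size when the ratio was at least 2 or at most 0.5 and the interval excluded 1. A fold against 0 reads was computed against a floor of 3 reads in the library. For each list of families the median log2 ratio was placed among 10000 random lists of the same size, each member drawn from the 10 families nearest in mean abundance, as a description of these libraries. The interval and the 2-fold rule were tested on simulated data with the same 46 families and depths in 200 runs, drawn with Poisson counting noise alone. Coverage near 95% is therefore fixed in advance, and the shares called are no error rates for differences between plants or library preparations. The interval held the true ratio in 95.1% of unchanged families, and 0.029% of these were called. For families simulated with a 3-fold difference 99.7% were called, and for a 4-fold difference 100.0%.

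The rule for named families was set before the data were examined, among families with at least 100 reads: the 10 with the highest mean number of reads per 1000000 (RPM), the 10 with the largest and the 10 with the smallest ratio among those at least 2-fold apart, and the 2 to 4 most abundant members of each list. A sequence was named when it led a named family or held more than 5% of the reads of a file. The lists were also set then: families that target transcription factors, small RNA pathway genes, copper proteins and disease resistance genes, families of phosphate and sulphate, of auxin and tasiRNA and of developmental phase, families reported as cold-responsive in other plants, and, as background, families known only from animals and families matched here only to moss or green alga names. For the moss and alga list only the rule was set then, and its members follow from the matches themselves. The targets named are textbook knowledge from other plants and were not measured here. Further sequences named for their shorter forms or as tRNA fragments, the 7 transcripts of the non-acclimated library and the overlap of families with Rfam were chosen after the values were seen.

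The 7 transcripts are all those with at least 1000 reads in one library and at least 50-fold fewer RPM in the other. Their longest open frames were compared with those in 1000 shuffles of each transcript. Phased transcripts were searched with 21 nt sequences of at most 5 hits, in windows of 9 cycles, on transcripts with at least 8 positions, with a hypergeometric score below 1.0e-06. Shorter forms are the leading sequence of a family without its last 1 to 3 nucleotides at the 3' end.

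The alternatives tried were other denominators (reads matched to miRBase or to transcripts, the median of ratios, trimmed-mean scaling with edgeR, the union without Rfam-matched reads), other minimums of reads, length limits, the leading sequence alone, matches without mismatch, sequences without an Rfam match, other fold thresholds and distinct sequences in place of reads. The smallest library totals, the union without the 7 transcripts, families by miRNA number and counts without star forms were added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with R 4.3.3 and edgeR 4.0.16 for the scaling factors alone.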

Results

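Small RNA was sequenced from mature leaves of the tea plant Camellia sinensis, cultivar Longjing 43, at 2 points of a natural winter. The non-acclimated leaves were collected on 1 December 2010 and the cold-acclimated leaves on 29 December 2010, and each state is represented by 1 library. The matched sequences of the non-acclimated library held 2476893 reads of 299983 distinct sequences, and those of the cold-acclimated library held 2212636 reads of 250703 distinct sequences. If the sequence numbers of the whole libraries follow falling read counts, as they do among the listed sequences, the libraries held at least 14799078 and 10531268 reads, of which the matched sequences are then at most 16.74% and 21.01%. With 1 library per state no spread between plants can be measured, so every ratio below compares these 2 libraries and not the conditions, and every interval is a 95% interval for counting error only. Ratios are given as cold-acclimated over non-acclimated, of reads per 1000000 matched reads (RPM), unless stated otherwise.

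In plants, miRNAs are mostly 21 nt and heterochromatic small interfering RNAs 24 nt long. The length profile covers only reads matched to assembled transcripts, so it does not show the shares of these classes in the leaves as a whole. Among reads matched to assembled tea transcripts, 21 nt was the most frequent length in both libraries, at 43.5% (43.5 to 43.6) of 1977468 reads in the non-acclimated and 42.0% (41.9 to 42.1) of 1631926 reads in the cold-acclimated library. Reads of 24 nt made up 14.5% (14.4 to 14.5) and 16.4% (16.3 to 16.4). Reads of 20 nt took 8.07% (8.03 to 8.11) of the non-acclimated and 4.988% (4.955 to 5.022) of the cold-acclimated library. The difference at 21 nt, where the cold-acclimated share was lower by reads, turned to 1.06 percentage points higher when distinct sequences were counted.

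**Figure D1:**
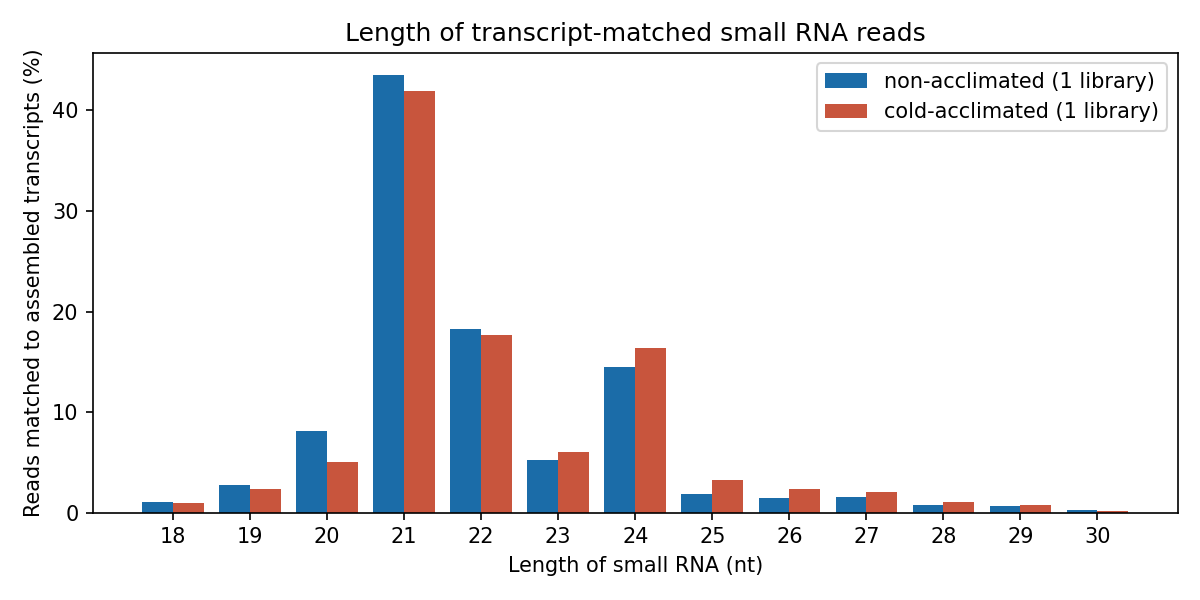
Length of the small RNA reads matched to assembled transcripts, from 18 to 30 nt on the horizontal axis, with the percentage of each library's matched reads on the vertical axis and 1 bar per library (blue, non-acclimated; red, cold-acclimated). Both libraries peak at 21 nt (43.5% and 42.0%) with a smaller peak at 24 nt (14.5% and 16.4%), and the 20 nt bar is 8.07% against 4.99%.

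Fragments of structural RNAs took a larger part of the cold-acclimated library. Reads matched to transfer RNA made up 5.50% (5.48 to 5.53) of the matched reads in the non-acclimated and 11.5% (11.4 to 11.5) in the cold-acclimated library, a ratio of 2.08 (2.07 to 2.09). Reads matched to ribosomal RNA took 15.1% (15.1 to 15.2) and 18.98% (18.93 to 19.03), a ratio of 1.25 (1.25 to 1.26), but as a share of the reads matched to Rfam classes their ratio was 0.862. Small nuclear RNA took 0.387% and 0.248% (ratio 0.640, 0.6188 to 0.6615), and small nucleolar RNA 0.142% and 0.109% (ratio 0.768, 0.729 to 0.809). A pair of tRNA fragments was picked after the values were seen. The 19 nt fragment GCGTTTGTAGTCCAACGGT stood at 2915 RPM in the non-acclimated and 11230.5 in the cold-acclimated library (ratio 3.85, 3.75 to 3.96), and the 20 nt fragment GGGGATGTAGCTCAGATGGT at 7574 and 12302 (ratio 1.62, 1.59 to 1.65).

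The lengths of these fragments, a sign of RNA quality, also differed. Fragments of 18 to 20 nt made up 52.72% (52.45 to 52.98) of the tRNA reads in the non-acclimated and 46.1% (45.9 to 46.3) in the cold-acclimated library. This difference of -6.585 percentage points was -2.97 without the 10 most abundant tRNA sequences of each library and -2.00 by distinct sequences. For rRNA the shares were 15.8% (15.7 to 15.9) and 11.89% (11.79 to 11.99), and without the 10 most abundant rRNA sequences of each library the difference turned, to 1.14 percentage points higher in the cold-acclimated library.

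A set of 7 short assembled transcripts, found after the data were examined, carried abundant small RNAs in the non-acclimated library alone. They held 162190 reads there, 6.55% (6.52 to 6.58) of the matched reads, and 8 reads in the cold-acclimated library, 18111-fold fewer in RPM (9191 to 41950). The reads came from 8212 distinct sequences on both strands, with 59.3% on the plus and 40.7% on the minus strand. Of these reads 87.65% were 20 to 22 nt long, 43.25% were 21 nt and 0.859% were 24 nt. On the other transcripts 58.9% of the reads were 20 to 22 nt long, with sequences matched to Rfam or miRBase, and so the known miRNAs, left out. No transcript with at least 1000 reads in the cold-acclimated library was at least 50-fold lower in the other library. Unigene59106_All, with 32 and 1206 reads (ratio 42.2), and Unigene57544_All, with 19 and 876 (ratio 51.6), came near these limits. Part of the length difference came from the 7 transcripts. Without them the difference in the 20 nt share, cold-acclimated minus non-acclimated, was -1.75 in place of -3.08 percentage points. At 24 nt it was 0.6825 in place of 1.898. The files pair no gene names with the transcripts.

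**Figure D2:**
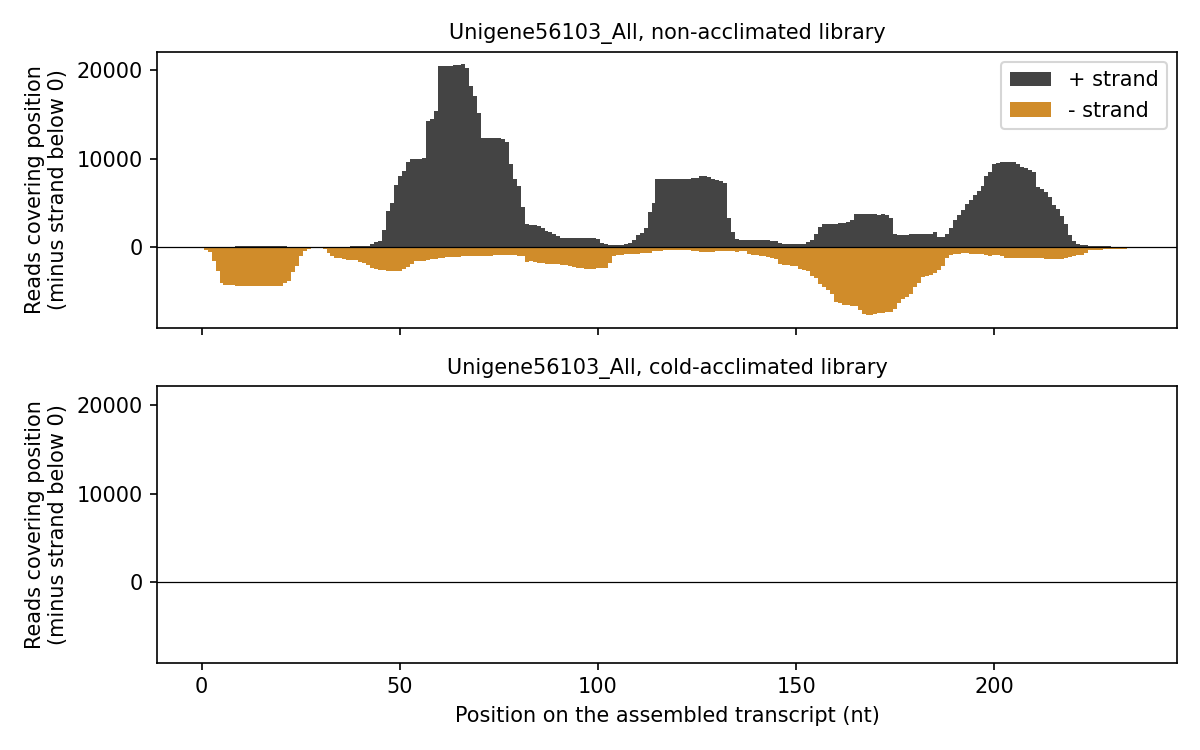
Small RNA reads covering each position of the assembled transcript Unigene56103_All, the one with most reads of the 7, in the non-acclimated (top) and cold-acclimated (bottom) library. The horizontal axis is the position on the transcript in nt, the vertical axis the number of reads covering it, with plus-strand reads above 0 and minus-strand reads below. In the non-acclimated library plus-strand coverage reaches 20679 reads at position 66 and minus-strand coverage 7656 reads, and the cold-acclimated library holds 3 reads, too few to be seen on this scale.

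The central question of the study was which miRNAs differ between the non-acclimated and the acclimated state. Reads with a miRBase match made up 29.2% (29.1 to 29.2) of the matched reads in the non-acclimated and 27.5% (27.5 to 27.6) in the cold-acclimated library, a ratio of 0.944 (0.9405 to 0.9469) that became 1.009 relative to transcript-matched reads and 1.185 relative to the smallest library totals. They fell into 396 miRNA families, 46 of which had at least 100 reads over both libraries. By size, 6 of these 46 families were at least 2-fold higher in the cold-acclimated library and 5 at least 2-fold lower, and 35 were neither. The interval lay above 1 for 18 families and below 1 for 13. The choice of denominator shifted every log2 ratio by a common amount, from -0.20 with trimmed-mean scaling to 0.33 with the smallest library totals, so the split of 6 higher and 5 lower became 10 and 4 without Rfam-matched reads in the denominator and 13 and 3 with the smallest library totals.

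**Figure D3:**
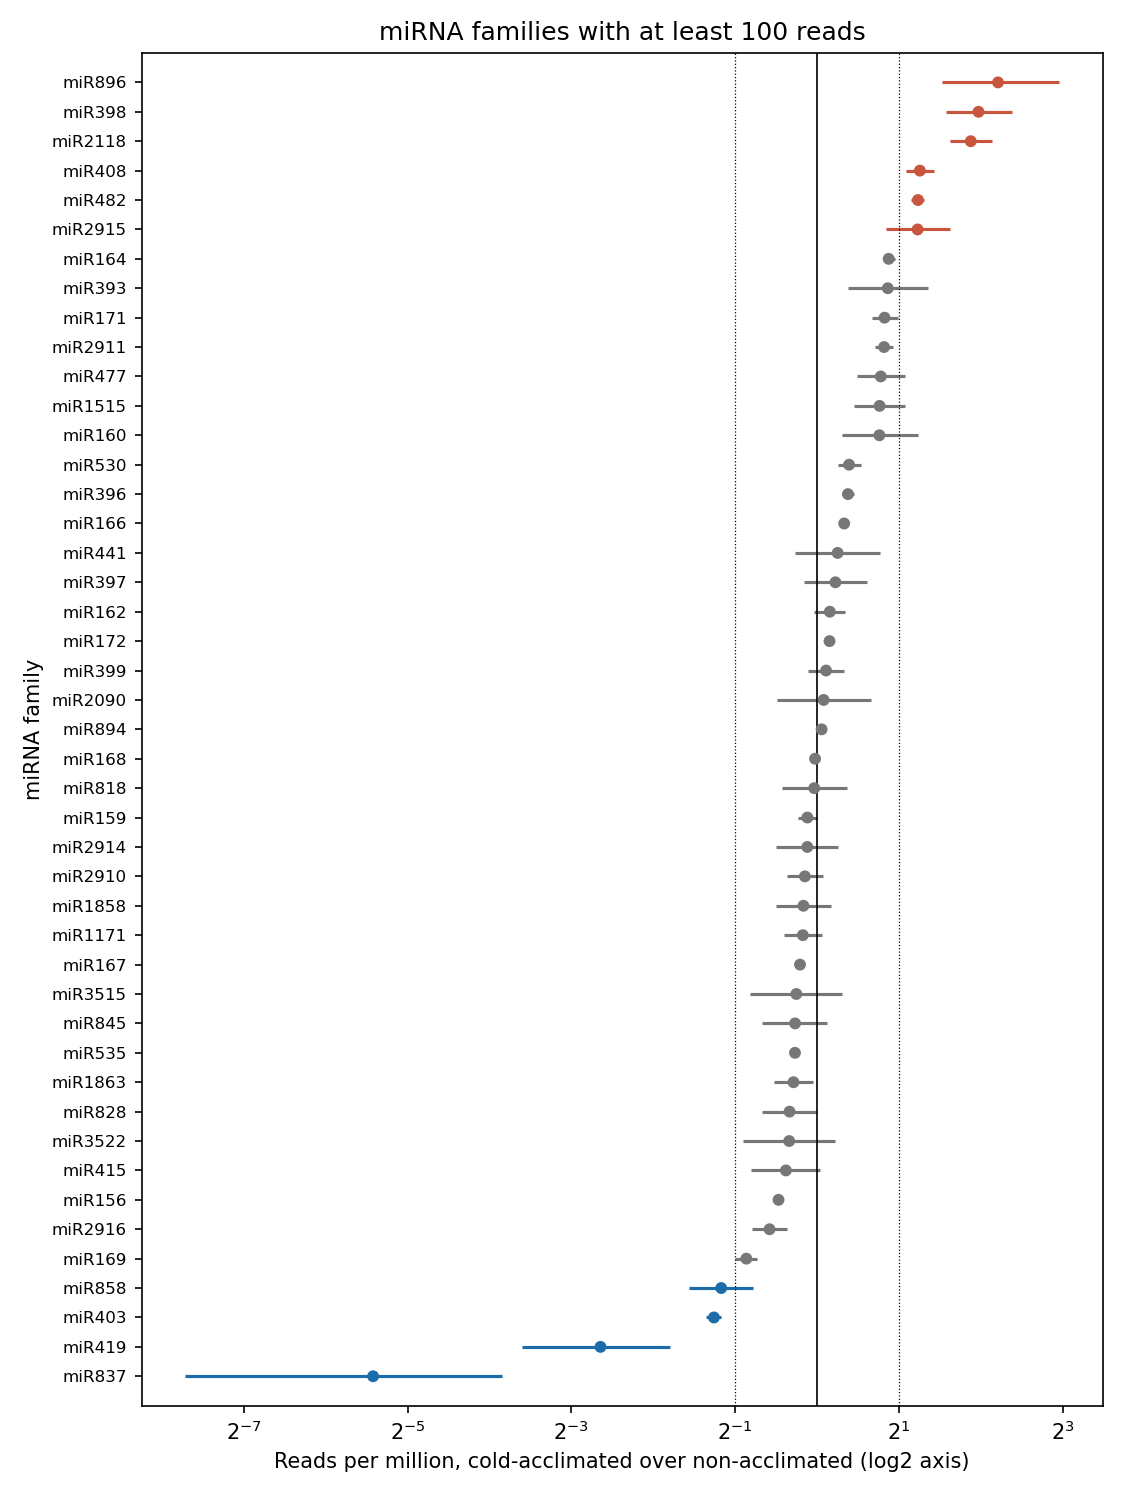
Ratio of RPM, cold-acclimated over non-acclimated, for the miRNA families with at least 100 reads over both libraries and any read in the cold-acclimated library, on a log2 axis with 1 row per family. Points are ratios, bars their 95% counting intervals, the solid line marks a ratio of 1 and the dotted lines ratios of 2 and 0.5. Red points are the 6 families at least 2-fold higher, from miR896 (4.63) to miR2915 (2.34), and blue points 4 of the 5 at least 2-fold lower, down to miR837. The remaining one, miR2659, had 0 reads in the cold-acclimated library and is not drawn.

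The families higher in the cold-acclimated library included members of 2 known groups. Both measured families that target disease resistance genes of the NBS-LRR class were higher: miR482 went from 767 to 1804 RPM (ratio 2.35, 2.23 to 2.49) and miR2118 from 69.4 to 255 (ratio 3.68, 3.10 to 4.39). Of the 3 measured copper families, which act on copper proteins, 2 were higher. These were miR398, a regulator of Cu/Zn superoxide dismutase, from 27.9 to 109 RPM (ratio 3.93, 2.99 to 5.21), and miR408, a regulator of plantacyanin, from 165 to 394 (ratio 2.39, 2.12 to 2.70). The third, miR397, which targets laccases, had a ratio of 1.17 (0.895 to 1.53). The median log2 ratio of the copper list was 1.26, at percentile 99.0 of 10000 random lists of the same size matched on abundance. It was 1.98 without star forms and 0.74 at a minimum of 10 reads, which adds miR857. With matches without mismatch it was 2.53, over miR398 and miR408 alone, since miR397 fell below 100 reads and miR408 kept only 161 reads. The median of the disease resistance list was 1.56 over 2 families. It was 1.23 at a minimum of 10 reads, which adds miR1507 (14 and 15 reads, ratio 1.20, 0.540 to 2.68). No sequence was counted in both miR482 and miR2118. Only 11 and 26 of the miR2118 reads came from sequences that share no 17 nt stretch with any sequence matched to miR482. The leading miR2118 sequence nevertheless differs from the miR482 leader, and had 103 and 335 reads (ratio 3.64, 2.91 to 4.59).

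Reads counted as the mature and as the star strand differed in their ratios for miR482 and miR408. Almost all reads counted as miR482 star came from 1 sequence of 20 nt, with 632 non-acclimated and 63 cold-acclimated reads. Whether that sequence comes from the same transcript as the leading miR482 sequence was not tested, so a shift between strands of 1 miRNA is not shown. The mature strand of miR482 had 1248 reads in the non-acclimated and 3924 in the cold-acclimated library (ratio 3.52, 3.30 to 3.75), while its star strand had 652 and 67 reads, 8.69-fold fewer in RPM (6.753 to 11.35). Its leading sequence TTTCCAAGTCCACCCATTCCTA took 62.9% of the family's reads in the non-acclimated and 95.6% in the cold-acclimated library. For miR408 the mature strand had a ratio of 3.95 (3.10 to 5.07) and the star strand 1.97 (1.71 to 2.26). The star strand of miR398 had only 10 and 13 reads (ratio 1.455, 0.5895 to 3.71) beside 4.345 (3.25 to 5.89) for the mature strand, and miR2118 had no star reads. The leading sequence of miR408 is a star form, ACGGGGACGAGACAGAGCATG with 309 and 538 reads, and counted alone it gave a log2 ratio of 0.96, below 2-fold. The leading sequence of miR398, TGTGTTCTCAGGTCGCCCCTG, matched positions 49 to 69 of the plus strand of the assembled transcript Unigene30704_All and had 29 and 156 reads (ratio 6.02, 4.03 to 9.29).

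The other 2 families at least 2-fold higher overlapped with tRNA. For miR896, with 8.88 and 41.1 RPM (ratio 4.63, 2.88 to 7.75), 99.1% of the reads over both libraries also matched tRNA in Rfam, and for miR2915, with 34.3 and 80.4 (ratio 2.34, 1.80 to 3.07), 94.3% did. Both fell below 100 reads when Rfam-matched sequences were left out, which left 4 families higher and 5 lower.

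Of the families lower in the cold-acclimated library, 2 have known targets. miR403, which targets the Argonaute gene AGO2, went from 1415 to 591 RPM, 2.39-fold lower (2.245 to 2.552). Its most abundant 21 nt sequence differed little, while shorter and 22 nt forms were lower. The leading 19 nt form TTAGATTCACGCACAAACT had 1568 and 494 reads, 2.84-fold fewer in RPM (2.56 to 3.14), and the 21 nt sequence TTAGATTCACGCACAAACTCG had 371 and 336 (ratio 1.01, 0.872 to 1.18). The 22 nt reads of the family numbered 197 and 75, 2.35-fold fewer in RPM (1.79 to 3.10). Counting only 21 nt sequences, the log2 ratio of the family was -0.50, and with the smallest library totals it was -0.93. miR858, which targets MYB transcription factors of the phenylpropanoid pathway, went from 80.3 to 35.7 RPM, 2.25-fold lower (1.73 to 2.96), with log2 ratios of -0.98 without Rfam-matched reads in the denominator and -0.84 with the smallest library totals.

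Of the other 3 lower families, 2 had few or no reads in the cold-acclimated library. miR2659 had 154 and 0 reads and was at least 45.9-fold lower when 3 reads are taken as the floor of the library. miR837 had 144 and 3 reads, 42.9-fold lower (14.4 to 210), and miR419 had 91 and 13 reads, 6.25-fold lower (3.48 to 12.2). Few reads of these 3 families matched miRBase without mismatch (0%, 0.680% and 9.615%), as was the case for miR482 (0.0509%), miR2118 (0.136%) and miR896 (0.885%), against 93.5% for miR858. When the other alignment count, whose meaning is not given, also had to be 0, the share was 0% for all of these families, miR858 included. In the non-acclimated library 31 miRBase-matched sequences with at least 10 reads, 1126 reads together, had no read in the other library, against 8 such sequences with 140 reads in the cold-acclimated library.

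The most abundant families differed less. The 6 largest held 95.2% of the miRBase-matched reads in the non-acclimated and 94.1% in the cold-acclimated library. They were miR167, which targets auxin response factors, with 85035 and 73654 RPM (ratio 0.866, 0.861 to 0.872), miR535 with 67948 and 56400 (ratio 0.830, 0.824 to 0.836), miR166, which targets class III HD-ZIP genes, with 51016 and 64205 (ratio 1.26, 1.25 to 1.27), miR156, which targets SPL genes, with 34785 and 25118.5 (ratio 0.722, 0.714 to 0.730), miR168, which targets AGO1, with 27463 and 27017 (ratio 0.984, 0.973 to 0.995), and miR172, which targets AP2-like genes, with 11447 and 12730 (ratio 1.11, 1.09 to 1.13). Next came miR894 (ratio 1.04, 1.01 to 1.07), miR164, which targets NAC genes (ratio 1.84, 1.74 to 1.93), and miR396, which targets growth-regulating factors (ratio 1.30, 1.24 to 1.37). None of these 9 families reached 2-fold, although miR164 had a log2 ratio of 1.06 without Rfam-matched reads in the denominator and 1.20 with the smallest library totals. For miR168, miR167, miR535, miR172 and miR894 the side of 1 on which the ratio lay changed with the denominator.

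Of the 16 fixed families that target transcription factors, miR157, miR165 and miR170 were counted within miR156, miR166 and miR171, and miR319 had 0 and 1 read. The other 12 were measured, and only miR858 passed 2-fold, in the lower direction. Their median log2 ratio was 0.018, at percentile 29.35, and its sign changed with the denominator, to -0.186 with trimmed-mean scaling, and with the choice of sequences, to -0.144 with matches without mismatch. Of the 3 small RNA pathway families miR403 was lower and miR168 and miR162 (ratio 1.11, 0.979 to 1.27), which targets the Dicer gene DCL1, were neither. The median of that list was -0.024, at percentile 31.02, and its sign changed with the denominator. For the 4 auxin and tasiRNA families measured, the ratios were 0.866 for miR167, 0.793 (0.629 to 0.997) for miR828, 1.70 (1.23 to 2.35) for miR160 and 1.82 (1.30 to 2.56) for miR393, which targets auxin receptors, with a median log2 ratio of 0.28 at percentile 71.8. That median was 0.81 at a minimum of 10 reads, which adds miR390 and miR394. It was -0.34 with matches without mismatch and -0.21 without star forms, where miR160 fell below 100 reads, and -0.21 at a minimum of 1000 reads, where miR167 alone was left. miR399, a regulator of phosphate uptake, was the 1 measured member of the phosphate and sulphate list, with a ratio of 1.08 (0.930 to 1.25). The developmental phase families miR156 and miR172 gave a median log2 ratio of -0.16, and neither reached 2-fold. The sign of that median changed with the denominator, to 0.029 without Rfam-matched reads and 0.17 with the smallest library totals.

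The list of families reported as cold-responsive in other plants had 12 measured members. Of these, miR398 and miR408 were at least 2-fold higher, 0 were lower and 10 were neither, among them miR166, miR156, miR168 and miR172. The median log2 ratio was 0.28, at percentile 82.35 of the random lists, and between 0.075 (trimmed-mean scaling) and 0.61 (smallest library totals) over the alternatives. Over all 8 lists 22 families were measured, 4 of them higher and 2 lower. The miRBase names came from 30 species codes, with 0 among the few animal codes looked for, such as human, mouse and fruit fly. This says nothing on contamination, since it would be fixed in advance if only plant names had been matched. Of 82 families matched here only to moss or green alga names, 3 had at least 100 reads, with miR896 higher and miR894 and miR1171 (ratio 0.887, 0.7555 to 1.041) neither.

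The same sequence led the family in both libraries for 32 of the 46 families, and for 15 of the 17 families with at least 1000 reads. The leader of miR167, TGAAGCTGCCAGCATGATCTAG, took 40.2% (40.0 to 40.4) and 50.4% (50.2 to 50.7) of its family, and the leader of miR166, TCGGACCAGGCTTCATTCCCC, 61.1% in both libraries. In the miR156 family the leader differed. The non-acclimated library was led by TTGACAGAAGATAGAGAGCAC, matched to the Arabidopsis miR157a, with 34200 reads there and 17278 in the cold-acclimated library (1.77-fold fewer in RPM, 1.74 to 1.80). The cold-acclimated library was led by CTGACAGAAGAGAGTGAGCAC, matched to the Arabidopsis miR156a, with 24860 and 25064 reads (ratio 1.13, 1.11 to 1.15). The 20 nt form of miR168, TCGCTTGGTGCAGGTCGGGA, had 5019 reads in the non-acclimated and 729 in the cold-acclimated library, 6.15-fold fewer in RPM (5.69 to 6.66), and its full 21 nt form TCGCTTGGTGCAGGTCGGGAA had 55530 and 53545 (ratio 1.08, 1.07 to 1.09).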

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

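The fold limit behind these 3 transcripts was chosen after the data were examined. Reads matched to Rfam or miRBase were left out here. Of the 1240 assembled transcripts with at least 100 other small RNA reads, which the comparisons of miRNA families do not use, 3 had at least 4-fold more reads per 1000000 (RPM) in the cold-acclimated library. The largest by reads, Unigene59106_All, had 32 reads in the non-acclimated and 1206 in the cold-acclimated library (ratio 42.2, 29.7 to 61.9), all on the minus strand in the cold-acclimated library, with 33.8% of them 20 to 22 nt long. Another had 19 and 876 reads (ratio 51.6, 32.9 to 86.1), and the third 9.5 and 92 reads, where reads on several transcripts are divided (ratio 10.8, 5.56 to 23.9). Their reads in the cold-acclimated library also lay on the minus strand alone, with 45.1% and 38.6% of 20 to 22 nt. In the other direction 13 transcripts had at least 4-fold fewer reads, among them the 7 with small RNAs of both strands. The files pair no gene names with these transcripts.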

How the results depend on the processing

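The alternatives with the smallest library totals, without the 7 transcripts, with families by miRNA number and without star forms were chosen after the data were seen. No paired analysis was possible because each group has 1 library and no label pairs them, and no library could be left out for the same reason. Leaving out sequences that match several families was not run, since each sequence has 1 listed match.

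Alternatives that left a called family under the minimum of reads gave no value for it, so between 11 (miR896) and 17 (miR408 and miR403) alternatives gave a value for each of the 11 families called higher or lower. Some of these could not change a ratio. Another minimum of reads repeats the main ratio of each family it keeps, as does leaving out star forms for a family that has none. miR482, miR2118, miR896, miR2659, miR837 and miR419 have no value with matches without mismatch. In the alternatives that gave a value, the 11 families kept their direction, and miR896, miR398, miR2118, miR482, miR2915, miR2659, miR837 and miR419 stayed at least 2-fold apart, while miR408 (1 alternative), miR403 (2) and miR858 (2) fell below 2-fold in those named in the report. Over the 404 alternative values of named families, 289 lay within the counting interval of the value reported, among them those that repeat it by construction, and 115 lay outside it. For families not called, 18 values had the other sign or, for miR894 with the median of ratios, were 0.

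The numbers of families, 6 higher and 5 lower, changed by more than 1.5 times in these cases. Higher families numbered 13 at a 1.5-fold limit, 10 without Rfam-matched reads in the denominator, 13 with the smallest library totals, 12 at a minimum of 10 reads or with no minimum, 2 at 1000 reads, 3 with 21 nt sequences only and 1 at a 4-fold limit. Lower families numbered 11 at a minimum of 10 reads, 12 with no minimum, 1 at 1000 reads, and 3 at a 4-fold limit, with matches without mismatch or with the smallest library totals. List members, 4 higher and 2 lower, numbered 7 and 1 without Rfam-matched reads in the denominator, 8 and 0 with the smallest library totals, 2 and 1 at 1000 reads and 2 and 1 with 21 nt sequences only. The share of families with the same leading sequence, 69.6%, was 88.2% at 1000 reads. A higher minimum leaves fewer families to count, and a denominator shifts all ratios alike. For the others the cause was not tested.

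Of the 133 alternative values of list medians, 63 lay within the counting interval of the value reported, 57 outside it without being reversed, and 13 were reversed. Of all 133, 22 had the other sign. The copper median, 1.26, ranged from 0.74 at a minimum of 10 reads to 2.53 with matches without mismatch, where miR397 is missing. The transcription factor median, 0.018, was -0.039 with the median of ratios, -0.186 with trimmed-mean scaling, -0.118 with no minimum, -0.144 with matches without mismatch, -0.115 without star forms and -0.080 without the 7 transcripts. The auxin and tasiRNA median was 0.81 at a minimum of 10 reads or with no minimum. The 13 reversed values follow. The small RNA pathway median was 0.060 per miRBase-matched reads, 0.091 per transcript-matched reads, 0.16 without Rfam-matched reads in the denominator, 0.30 with the smallest library totals, 0.085 with 21 nt only, 0.11 with leading sequences only, 0.00039 with matches without mismatch and 0.029 without star forms. The developmental phase median was 0.029 without Rfam-matched reads in the denominator and 0.17 with the smallest library totals. The auxin and tasiRNA median was -0.21 at 1000 reads, where miR167 alone was left. It was -0.34 with matches without mismatch and -0.21 without star forms, both without miR160, which fell below 100 reads. The common shift explains the reversals with another denominator by construction, and the loss of members explains those of the auxin and tasiRNA list. For the other sequence subsets the cause was not tested.

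Shares moved by more than their narrow counting intervals under nearly every alternative. The differences at 20, 21 and 24 nt, in percentage points, were -2.27, -3.13 and 1.30 in the union of the files, -4.00, 1.06 (reversed) and 3.34 by distinct sequences, -4.36, -0.479 and 3.10 without Rfam or miRBase matches, -3.95, -1.70 and 1.35 without the 10 most abundant sequences, and -2.96, -1.82 and 1.74 with at least 2 reads. Without the 7 transcripts they were -1.75 at 20 nt and 0.6825 at 24 nt. The ratios of rRNA, tRNA, snRNA and snoRNA were 0.862 (reversed), 1.43, 0.440 and 0.528 as shares of Rfam-matched reads, 1.34, 1.84, 0.759 and 0.941 by distinct sequences, 1.574, 2.61, 0.803 and 0.964 with the smallest library totals, and 1.17, 1.94, 0.598 and 0.7175 without the 7 transcripts. With at least 2 reads, rRNA, snRNA and snoRNA were at 1.245, 0.611 and 0.721. The ratio of the miRBase-matched share was 1.009 per transcript-matched reads, 1.08 by distinct sequences and 1.185 with the smallest library totals, all reversed, 0.935 without the most abundant sequence, 0.9400 with at least 2 reads and 0.882 without the 7 transcripts. The 18 to 20 nt share of tRNA fragments differed by -2.00 by distinct sequences and -2.97 without the 10 most abundant, and that of rRNA by -0.779 and 1.14 (reversed). Apart from the change of denominator, the cause was not tested. Depth limits the families near 100 reads, whose intervals span over 1.5-fold, and what lies outside the matched sequences was not analysed here.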

Other observations

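All tests in this part were chosen after the results were seen, apart from the planned denominators. The 6 differences in the 18 to 20 nt share of tRNA and rRNA fragments were planned values, put to use as a test afterwards.

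Of the 7 listed families too small for the main comparison that had a ratio, 2 had an interval above 1, 0 below 1 and 5 including 1. miR390, which starts tasiRNA production, had 14 and 44 reads (ratio 3.52, 1.89 to 6.95), and miR395, which acts on sulphate assimilation, 22 and 60 (ratio 3.05, 1.845 to 5.227). Of the 13 named families with enough reads of both strands, the ratio of the star strand was below that of the mature strand for 7, above it for 2 (miR167 and miR156) and overlapped it for 4. The star strand of miR167 had a ratio of 1.90 (1.64 to 2.21) beside 0.865 (0.859 to 0.870) for its mature strand. The star strand of miR168 had 4188 and 1580 reads, 2.37-fold fewer in RPM in the cold-acclimated library (2.23 to 2.51), beside a ratio of 1.02 (1.01 to 1.03) for its mature strand, and the miR396 star strand had a ratio of 0.5745 (0.488 to 0.674) beside 1.44 (1.36 to 1.52). Of the miR2916 and miR2914 reads, 99.6% and 95.8% also matched rRNA.

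Of the reads on the 7 transcripts with small RNAs in the non-acclimated library alone, 87.65% were 20 to 22 nt, against 55.9% of that library's rRNA fragments. Both strands were well covered. These values argue against degraded RNA of a contaminating organism, but the limits for this comparison were set when the values were already known. The comparison covers degraded RNA alone, and whether other RNA of a contaminating organism was present was not tested. Small interfering RNAs that the plant made from a virus stay open, as a hypothesis without a test that favours them: 4 of the 7 transcripts had a longest open frame longer than in 95% of their shuffles, but a coding transcript of the plant would show the same. An effect of cold acclimation cannot be told apart from a difference between the plants sampled, since there is 1 library per group. No search against known viruses was made. miR2659 and miR837, with 0 and 3 reads in the cold-acclimated library, lay on none of the assembled transcripts, and whether they have the same source was not tested.

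Shorter forms of miRNAs were more frequent in the non-acclimated library for 5 of 12 families tested, more frequent in the cold-acclimated library for 2 and neither for 5, among them miR403, whose leading sequence is itself a 19 nt form. Gel size selection alone would shift families of the same length alike, but the log2 change for miR168 differed from that for miR166 by -2.66, both with 21 nt leaders. More trimmed RNA in the non-acclimated library cannot be decided, because the values go both ways: 5 of 6 differences in the 18 to 20 nt share of rRNA and tRNA fragments were lower in the cold-acclimated library, the exception being rRNA without its 10 most abundant sequences (1.14 percentage points higher), while the shorter forms of miR156 and miR894 were more frequent there. A difference in trimming or tailing that is specific to some families also stays open as a hypothesis, and an effect of cold acclimation was not tested, for want of replicates.

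The higher reads of miR482 and miR2118 in the cold-acclimated library did not depend on the denominator, as the lowest log2 ratio of either family over the denominators tried was 1.03. No sequence was counted in both families. Leaving out miR2118 sequences that share 17 nt with any miR482 sequence gave a ratio of 2.65 (1.26 to 5.93), on 11 and 26 reads. That filter cannot decide whether the 2 families are higher independently, because it also takes out the leading miR2118 sequence, with 103 and 335 reads. This leading sequence differs from the miR482 leader and had a ratio of 3.64 (2.91 to 4.59) by itself. If these families start more phased small RNAs, those may rise too, and the median ratio of 21 nt reads on 17 phased transcripts was 1.24 (0.878 to 1.43). That test decides nothing, because random positions gave 10 such transcripts among 2441. An effect of cold acclimation stays open and untested.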
